A study of Mus musculus with 20 samples.

How the data were processed

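Processed tables of the series were used as deposited, and no reads were aligned here. The authors' raw tables hold a count per miRNA and library, per the labels from Illumina small RNA libraries made from Trizol-extracted, DNase-treated RNA. The submitters' processing notes name CASAVA 1.8.2 and DESeq2 (version not given) and the builds GRCm38 and mm10. The aligner, the miRNA annotation and the handling of reads that fit several copies are not given in the sources used here. The deposited normalized signal values are the authors' counts divided by a size factor per library, checked from the ratios of both tables. The deposited log2 values come from the authors' variance-stabilized table made with DESeq2, and for the most abundant miRNAs they differed from the log2 of the normalized count by at most 0.000512 (male tables) and 0.000292 (female tables). Both of these derived tables served for checks only. All tests used the counts.

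Samples were grouped by the line and day in their labels into 10 groups of 2. In both lines the day 0 samples of experiment diff3 carry the cell-type label of differentiating cells (ESCs-EpiSCs), while their titles and day label give day 0. They were grouped by the day label, and every change against day 0 uses them. The experiment name in the labels (diff2 and diff3) gave the replicate numbers 2 and 3. There were 1091 miRNAs in the male table, 1109 in the female one and 1063 in both. Only the shared ones were compared between lines, since a miRNA missing from a table has no value there. Those only in the male table reached a total of at most 3 over its 10 libraries, and those only in the female table at most 339. Of the shared miRNAs 28 had 0 in all 20 libraries.

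Changes were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests on all 20 libraries, with 1 coefficient per group, TMM scaling and filterByExpr by group, which kept 813 miRNAs and 99.997% of the counts. The fit had 10 residual degrees of freedom, a common dispersion of 0.171 and a median prior of 5.08 degrees of freedom. TMM factors lay between 0.551 and 1.43. P-values were adjusted by the Benjamini-Hochberg method within each contrast at 0.05, and the SE of a log2 change is its size over the root of its F. CPM in the text are counts per library total scaled by the TMM factors, as are the log2 changes, so they differ from plain counts per total. Shares in percent, the floors per library and the 10 CPM filter use plain totals. Depth limits what can be seen: 3 counts, allowed by a count of 0, were 0.166 to 0.422 CPM, and where a group had 0 the fold is a bound against 3 counts over the group.

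Lists of miRNAs (22, with at least 3 tested members) were tested with camera (limma 3.58.1) on the edgeR fit with a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over lists within each contrast. Of 330 pairs of list and contrast 118 passed 0.05 with the preset value and 10 with an estimated correlation. The 10 were let-7 at female days 4 and 10 and male day 10, Dlk1-Dio3 at female day 4, miR-302 at male day 10, the X-linked, testis and miR-322 lists between the lines at day 0, and the X-linked and miR-322 lists in the late interaction. Positions and host genes came from GENCODE M21 by miRNA name, found for 1110 of 1137 mature names, and miRNAs with several loci are given with 1 of them. A miRNA was placed in an exon where any exon of any transcript of the host gene overlapped it. Such a miRNA may therefore lie in an intron of other transcripts of that gene.

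The design, the lists, the alternatives and the rule for naming miRNAs were fixed before the data were examined. The rule took miRNAs past an adjusted p of 0.05, with a mean of at least 50 CPM in the higher group and all libraries of a group above all of the other (averaged contrast: the same direction at all 5 stages). It named the 10 highest and 10 lowest for the late changes and the averaged contrast, 5 and 5 at day 4 and for the late interaction (50 CPM in any of its 4 groups, no rule on single libraries), the 10 most abundant at day 0 and late, and up to 4 members per list. Alternatives were RLE and total-count scaling, no filter, a mean of at least 10 CPM, the replicate as a block, DESeq2 1.42.0, each line fitted alone and leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups. A block within stages and libraries without the testis cluster were added after seeing the data.

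Whether the experiment numbers pair samples across lines was checked from deviations of log2 CPM from their group means. Libraries of the same stage and experiment in both lines correlated at 0.130 to 0.554 (median 0.393), all 5 above 0.1. Same-line pairs of different stages had a median of 0.0767 and other pairs 0.121. Between experiments, 22 of 813 miRNAs were called. The tests were also tested on simulated data with 200 changed miRNAs. For late female cells edgeR recovered 9.20% of 2-fold and 61.3% of 4-fold changes and called 4 of 596 unchanged miRNAs, for the averaged contrast 72.2% and all of them with 3 of 600, and for the lines at day 0 10.8% and 56.3% with 1 of 600. DESeq2 recovered 20.7% and 72.6%, 79.4% and all, and 17.2% and 62.1%, with 8, 6 and 4 unchanged miRNAs called. A simulated shift of let-7 gave camera an adjusted p of 4.89e-42, with 0 of 20 unmoved lists called. The simulated miRNAs were drawn independently of each other, so this does not test the preset correlation on real lists. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.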

Results

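MicroRNAs (miRNAs) were counted by small RNA sequencing in a male (E14) and a female (PGK) mouse embryonic stem cell line during conversion to epiblast stem cells, the primed pluripotent state that resembles the post-implantation epiblast. Day 0 cells grew in 2i medium, which holds naive cells with inhibitors of Mek and Gsk3, and were then moved to N2B27 with Activin A and Fgf2 on fibronectin. Each line was followed in 2 differentiation experiments (replicates 2 and 3 after the labels) at days 0, 4 and 10, and in a pair of windows at days 19 to 23 and 27 to 30, the latter called late here. The 20 libraries formed 10 groups of 2. Each sex was represented by 1 line, so sex and line cannot be separated, and the stages of a line share its day 0 libraries. The p-values measure the spread between these differentiation experiments.

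Total miRNA counts (M, mega) in the male line, replicates 2 and 3 in turn, were 13.5 and 15.6 M at day 0, 14.8 and 8.88 M at day 4, and 18.0 and 7.36 M at day 10. They were 7.11 and 9.29 M at days 21 and 19, and 9.27 and 9.985 M at days 27 and 30. Female totals were 12.4 and 10.8 M at day 0, 15.7 and 10.6 M at day 4, 13.3 and 9.89 M at day 10, 7.50 and 9.55 M at days 23 and 21, and 8.26 and 9.20 M at day 29 in both experiments. Between 864 and 923 miRNAs were detected per library, and the 10 most abundant took 44.7% to 60.4% of the counts. A count of 0 allowed up to 3 counts, which was 0.166 to 0.422 CPM of the plain total depending on the library. Without molecular identifiers, such floors cover counting error only. Levels are CPM scaled by the TMM factors as mean ± SD (n = 2 in every group), shares are percent of plain counts, and log2 changes are given ± their SE with p-values from edgeR's quasi-likelihood test, adjusted by the Benjamini-Hochberg method over 813 miRNAs. Positions are on GRCm38.

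At day 0 the highest mean level in both lines was that of miR-295-3p (chromosome 7, 3220773 to 3220841, intergenic), a member of the miR-290 cluster that is typical of mouse embryonic stem cells, at 171670.0 ± 33134 CPM in the female and 170662 ± 28871 CPM in the male line. By the mean over the libraries of both lines it was followed by miR-182-5p, miR-92a-3p, miR-127-3p, miR-27b-3p, miR-298-5p, miR-292-5p, miR-26a-5p, miR-16-5p and miR-22-3p. Late cells were led by miR-92a-3p (chromosome 14, 115044427 to 115044506, an exon of Mir17hg, with a further copy elsewhere) at 86123 ± 4532 and 89126 ± 1142 CPM. In late cells, by the same mean, miR-27b-3p, miR-292-5p, miR-26a-5p and miR-16-5p had left the 10 most abundant, and miR-541-5p, miR-99b-5p, miR-434-3p and miR-411-5p had entered. By the late stage miR-27b-3p, miR-26a-5p and miR-16-5p fell, with log2 changes of -1.25, -1.73 and -1.27 in the female line and -1.90, -1.91 and -1.23 in the male line (edgeR adjusted p at most 0.00328). Within each line the day 0 libraries had the lowest values on the first principal component, which held 52.7% of the variance, and the second held 17.0%. Across the lines a female day 4 library (-24.4) lay below a male day 0 library (-20.0). Replicates correlated across miRNAs, which are not independent replicates, at r = 0.975 to 0.993, and their counts differed by far more than sampling noise, with a chi-square per degree of freedom of at least 351.6.

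**Figure D1:**
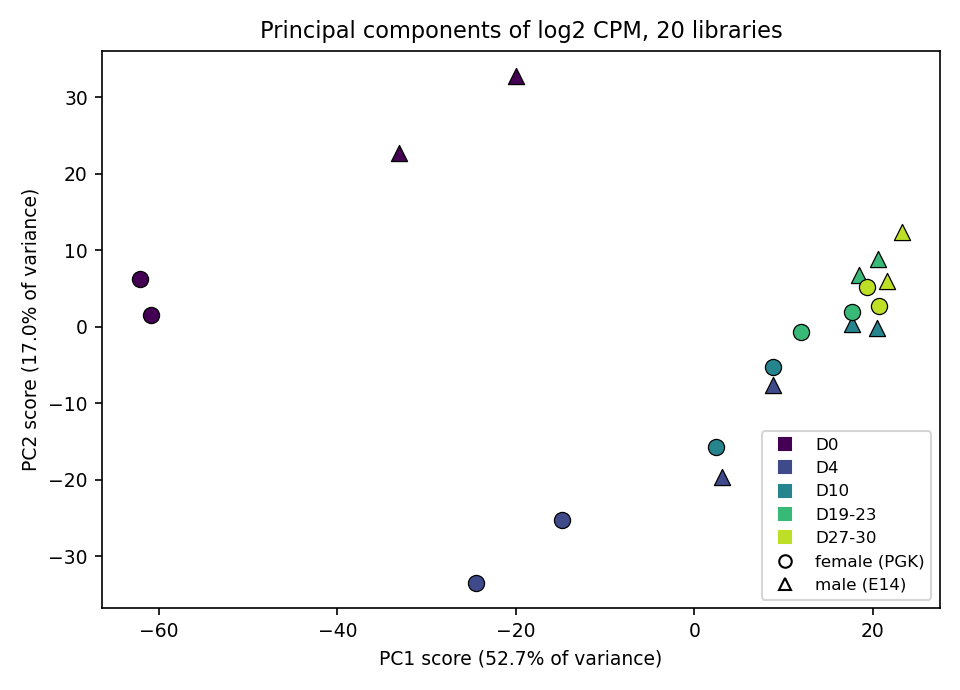
Principal components 1 and 2 (52.7% and 17.0% of the variance) of log2 CPM, 1 point per library, coloured by stage, with circles for the female and triangles for the male line. Day 0 libraries lie at component 1 values of -62.1 to -20.0, and the 4 late libraries lie between 19.4 and 23.2.

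The first comparison asked which miRNAs change as naive cells enter the primed state. Within 4 days of the switch, the miR-302 cluster, which marks primed pluripotent cells, rose steeply in both lines. The cluster lies between genes on chromosome 3 (127545228 to 127545807). In the female line miR-302a-3p went from 41.8 ± 1.46 to 5317 ± 1150.5 CPM (log2 change 6.99 ± 0.51, adjusted p = 5.31e-07), and in the male line from 91.7 ± 31.7 to 3755 ± 1572 CPM (5.36 ± 0.47, adjusted p = 3.65e-06). All 10 measured arms of the cluster passed the test at all 4 later stages in both lines, over all miRNAs and adjusted over the list alone. Their median log2 change in the female line was 6.90 at day 4, 7.33 at day 10, 6.52 at days 19 to 23 and 6.52 in late cells. In the male line the medians were 5.98, 7.06, 5.82 and 6.05. Summed, the cluster took 0.0153 ± 0.00171% of all counts at day 0 and 1.68 ± 0.369% in late female cells, and 0.0370 ± 0.0212% and 2.95 ± 0.826% in the male line, with the highest share, 5.43 ± 0.485%, in male day 10 cells. Against all other miRNAs, camera gave the list adjusted p-values of 4.31e-14 at female day 4 and 2.14e-11 at male day 4 with a preset correlation. With an estimated correlation these were adjusted p = 0.0751 and adjusted p = 0.162. At male day 10 the call held (adjusted p = 0.037 with an estimated correlation).

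Over the same 4 days the let-7 family, which accumulates in differentiated cells, fell steeply. The most abundant, let-7f-5p (2 genes, 1 of them at chromosome 13, 48537829 to 48537917, an exon of 6720427I07Rik), went from 20839 ± 3146 to 981 ± 289 CPM in the female line (-4.41 ± 0.39, adjusted p = 2.78e-06) and from 7050.2 ± 567 to 387 ± 61.0 CPM in the male line (-4.19 ± 0.38, adjusted p = 3.75e-06). In late cells let-7f-5p remained below day 0, with changes of -4.97 and -3.85 on the log2 scale. Of 21 measured members, 19 were lower at female day 4 and 17 at male day 4 (20 and 18 adjusted over the list alone), with medians of -4.31 and -4.19. In late cells 18 were lower and 1 higher in the female line, and 15 lower and 1 higher in the male line (medians -4.20 and -3.62). The higher one differed, let-7c-1-3p in female and let-7e-3p in male cells. The family's share of all counts went from 3.91 ± 0.488% to 0.186 ± 0.0237% in 4 days in female cells and from 1.75 ± 0.0217% to 0.117 ± 0.0289% in male cells. It was 0.300 ± 0.0592% and 0.268 ± 0.102% in late cells. By camera the fall had an adjusted p of 5.68e-18 at female day 4, which held with an estimated correlation (adjusted p = 0.0341), and of 1.68e-13 at male day 4, which did not (adjusted p = 0.13 with an estimated correlation). At day 10 both calls held with an estimated correlation (adjusted p = 0.0464 and 0.037).

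The maternally expressed miRNAs of the imprinted Dlk1-Dio3 region of chromosome 12 rose early and stayed a large part of all counts. In the female line 81 of 102 rose at day 4 (84 adjusted over the list alone), and their summed share went from 10.1 ± 2.57% to 37.2 ± 0.736%. In the male line 73 rose (76 adjusted over the list alone), and the share went from 11.01 ± 1.30% to 27.1 ± 0.369%. The most abundant, miR-127-3p (109592846 to 109592915, intergenic), went from 36226 ± 10001 to 192075 ± 66276 CPM in female cells (2.41 ± 0.45, adjusted p = 0.000717) and from 38668 ± 8626 to 104279 ± 35938 CPM in male cells (1.43 ± 0.44, adjusted p = 0.0164). At the same stage miR-434-3p rose by 1.88 in female cells and miR-411-5p by 2.21 and 1.35 in female and male cells, while miR-541-5p (an intron of Mirg) rose in female cells (2.49) and missed the threshold in male cells (1.25 ± 0.59, adjusted p = 0.0975). In late cells 61 members were higher than at day 0 in the female line and 24 were higher and 2 lower in the male line (67 and 20 higher adjusted over the list alone). The medians were then 1.36 and 0.66, and the shares 27.6 ± 1.77% and 18.2 ± 0.652%. The female day 4 rise had a camera adjusted p of 5.10e-23 (0.0341 as adjusted p with an estimated correlation). The male day 4 rise had 3.00e-12, and adjusted p = 0.162 with an estimated correlation.

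**Figure D2:**
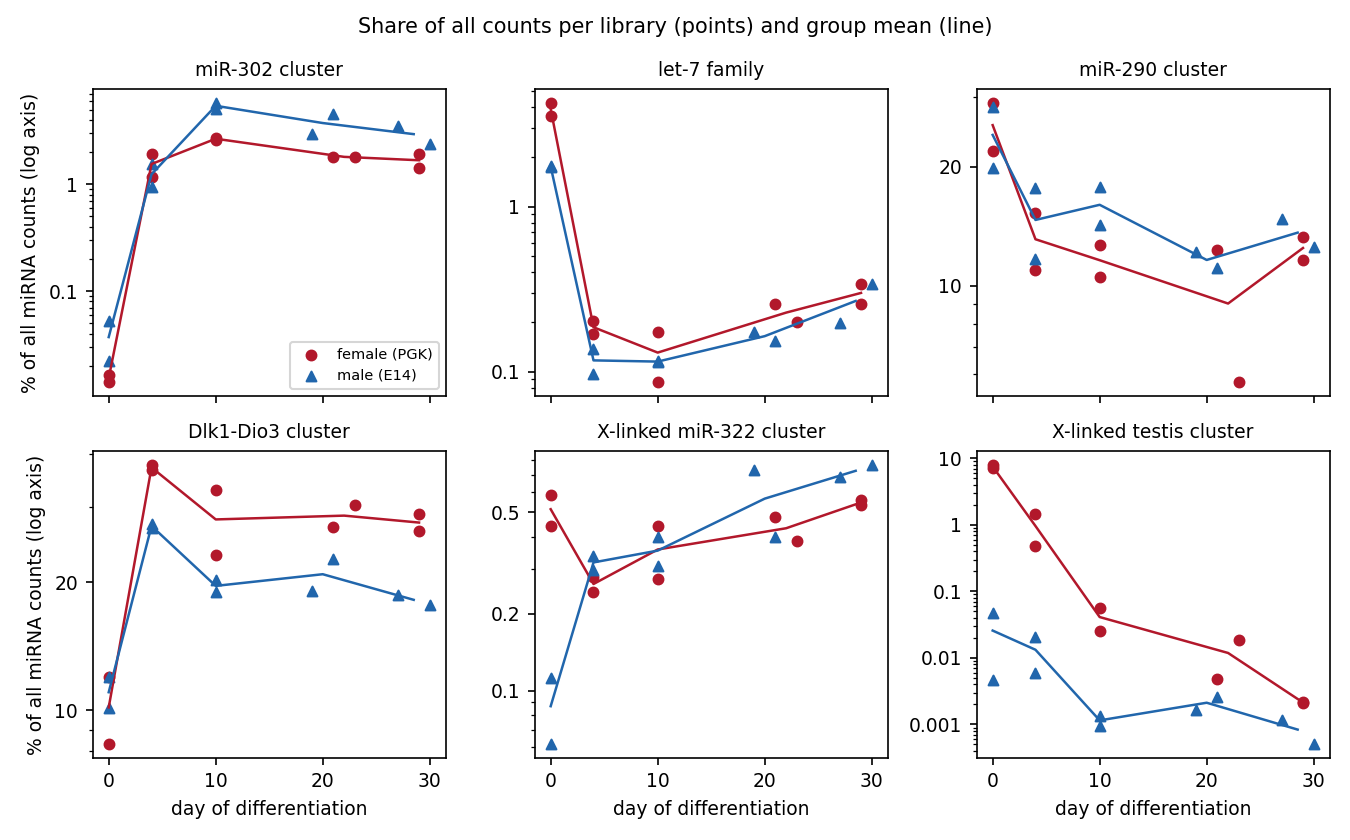
Share of all miRNA counts (percent, log axis) against day for 6 groups of miRNAs, 1 point per library, with lines through the group means of the female and male lines. The miR-302 cluster climbs from 0.0153% and 0.0370% at day 0 to 1.68% and 2.95% in late female and male cells, while the let-7 family drops from 3.91% and 1.75% to 0.300% and 0.268%.

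The miR-290 cluster (chromosome 7, 3218919 to 3220841 for the members named here) took a smaller mean share of counts in late cells than at day 0. By the late stage miR-295-3p fell to 69819.6 ± 2148 CPM in female cells (-1.30 ± 0.30, adjusted p = 0.00269) and to 63915 ± 8808 CPM in male cells (-1.42 ± 0.30, adjusted p = 0.00225), and stayed among the 10 most abundant miRNAs. Its neighbours miR-292-5p, miR-291a-5p and miR-293-3p changed by -1.81, -1.93 and -1.26 in female cells and -1.82, -1.41 and -1.77 in male cells. Of 14 members, 0 were lower at day 4 by edgeR in the female line, with a list median of -0.61 (camera adjusted p = 0.102), and 1 was lower in the male line, with a median of -0.55 (adjusted p = 0.149). That 1 was miR-293-3p (-0.90 ± 0.35, adjusted p = 0.0475). At days 19 to 23 13 and 12 were lower, and in late cells 11 and 11 (13 and 12 adjusted over the list alone). The late medians were -1.40 and -1.41 (camera adjusted p = 0.0028 and 0.00114; adjusted p = 0.553 and 0.566 with an estimated correlation). The cluster took 25.5 ± 4.97% and 24.1 ± 5.93% of all female and male counts at day 0, 13.1 ± 3.05% and 14.7 ± 4.19% at day 4 and 12.5 ± 1.204% and 13.6 ± 1.54% in late cells.

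Of the miRNAs that met the rule for naming, the largest late rise in both lines was that of miR-375-3p (chromosome 1, 74900658 to 74900721, intergenic), best known from pancreatic islets. It went from 9.06 ± 5.02 to 4119 ± 1275 CPM in the female line (8.83 ± 1.15, adjusted p = 3.01e-05) and from 10.9 ± 0.504 to 5632 ± 5655 CPM in the male line (9.01 ± 1.16, adjusted p = 3.73e-05). Next to it and the miR-302 cluster, miR-181a-1-3p (chromosome 1, an intron of Gm4258) rose to 212 ± 62.3 CPM in late female cells (6.88) and miR-489-3p (chromosome 6, an intron of Calcr) to 61.4 ± 4.08 CPM in late male cells (5.05). The deepest fall shared by both lines was that of miR-211-5p, encoded in an intron of Trpm1 (chromosome 7, 64205806 to 64205911). It went from 1823 ± 488 CPM to 15.9 ± 5.45 at day 4 and 0.297 ± 0.0950 in late female cells, and from 2318 ± 626 to 19.2 ± 11.03 and 0.301 ± 0.312 CPM in male cells (-12.50 and -12.83 on the log2 scale by the late stage). Its other arm, miR-211-3p, fell at female day 4 (-7.39), was down to 2 counts at male day 4 and had 0 counts in late male cells, at least 1234-fold below its 143 ± 25.9 CPM at male day 0 against a floor of 3 counts over the group. The cardiac and muscle miRNA miR-499-5p, in an intron of Myh7b, fell (-5.04 and -6.05), as did miR-150-5p (-4.77 and -5.11).

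Outside these groups other miRNAs rose by day 4. In both lines miR-488-3p, in an intron of Astn1 (chromosome 1, 158505625 to 158505733), rose from 0.556 ± 0.171 to 79.5 ± 11.4 CPM (female, 7.12) and from 1.62 ± 1.07 to 139.8 ± 52.7 CPM (male, 6.44). In male cells miR-670-3p (chromosome 2, an exon of Mir670hg) went from 0.163 ± 0.0273, which was 4 counts in the group, to 62.2 ± 8.58 CPM (8.49), and miR-1298-5p (an intron of Htr2c on the X chromosome) from 2 counts to 73.4 ± 27.4 CPM. The lowest at day 4 after miR-211 were let-7b-5p (-5.24, female), miR-98-5p (-5.24 and -5.11), let-7g-5p (-5.02, male) and miR-5114 (-5.09 and -6.32). The last overlaps an exon of Scd2.

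The miR-34b/c pair of chromosome 9 (51103034 to 51103645), known as targets of p53, rose at day 4. From 335 ± 77.8 and 226 ± 30.8 CPM at day 0, miR-34c-5p went to 4531 ± 569 and 3802 ± 1842 CPM in female and male cells (3.76 and 4.07), and miR-34b-5p rose by 3.73 and 4.16. By contrast miR-34a-5p did not pass the test in the female line at any of the stages given here (0.36 at day 4, -0.41 late) and fell in late male cells (-1.98 ± 0.56, adjusted p = 0.0121). Of 9 members of the miR-34 family 7 rose at day 4 in each line (7 and 7 adjusted over the list alone), with camera adjusted p-values of 0.00242 and 0.00244 and, with an estimated correlation, adjusted p = 0.438 and 0.356. Among miRNAs of at least 10 CPM these calls ended (0.0796 and 0.150). In late female cells the list's median was 3.24 (adjusted p = 0.0488; adjusted p = 0.553 with an estimated correlation), and it missed the threshold at 10 CPM or more (0.194), with the replicate block (0.0582) and without day 0 female replicate 2 (0.123).

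The miR-99/100 and miR-125 miRNAs, some of which share transcripts with let-7 genes, rose by the late stage. In late cells miR-99b-5p, in an intron of Spaca6 (chromosome 17, 17830188 to 17830257), was higher than at day 0 by 2.07 and 2.50, miR-125a-5p by 1.84 and 2.26 and miR-125b-5p by 4.80 and 4.35 in female and male cells. Of 10 members 9 rose in the female and 10 in the male line (10 and 10 adjusted over the list alone; camera adjusted p = 0.00122 and 0.000244, and adjusted p = 0.131 and 0.177 with an estimated correlation). At day 4 only 2 and 4 had passed the test.

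The epithelial miR-200 family lies on chromosomes 4 and 6, which no test compared. The chromosome 4 members miR-200b-3p (156055681 to 156055750, an intron of Ttll10), miR-200a-3p and miR-429-3p rose at female day 4 by 2.60, 1.89 and 1.72, and on chromosome 6 miR-200c-3p (1.43) and miR-141-5p (1.86) rose as well. The chromosome 6 pair miR-141-3p and miR-200c-3p (124717914 to 124718390, an intron of Gm15884) fell by the late stage, with changes of -4.23 and -3.61 in the female line and -7.31 and -5.23 in the male line, where miR-141-3p went from 1138 ± 455 to 7.18 ± 2.04 CPM. At female day 4 8 of 10 rose (9 adjusted over the list alone; camera adjusted p = 0.00774, adjusted p = 0.587 with an estimated correlation). In late cells 3 were higher and 3 lower in the female line, where the median (1.10) and mean (-0.44) had opposite signs and the test pointed down without a call (adjusted p = 0.604). In the male line 4 were lower (median -0.82, mean -2.78; adjusted p = 0.00114, and 0.454 as adjusted p with an estimated correlation).

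Between day 10 and the late stage edgeR called few miRNAs, and miR-141-3p, miR-141-5p and miR-200c-3p were called in both lines. The 4 called in the female line were all lower: miR-141-3p (-4.66), miR-141-5p (-4.67), miR-200c-3p (-4.27) and miR-465b-5p (-5.44). Of the 6 called in the male line miR-141-3p (-5.04), miR-141-5p (-4.72) and miR-200c-3p (-4.02) were lower, and miR-10a-5p (8.61), miR-615-3p (6.29) and miR-760-3p (2.15) higher. Both sets were named after their values were seen, because the counts were so small. The late male levels of miR-10a-5p and miR-615-3p lay mainly in replicate 3 (2614 and 88.4 CPM, against 46.6 and 6.44 CPM in replicate 2). At an unadjusted p under 0.05 there were 73 and 122, and DESeq2 called 33 and 28. Female calls numbered 28 with the replicate block and 15 without a filter on low counts, and male calls 15 without that filter. Fitted on its own line, the test called 19 and 3. Male calls numbered 2 without late male replicate 3 and 20 without late male replicate 2.

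In the female line edgeR called 318 of 813 miRNAs at day 4 against day 0 (199 higher, 119 lower), 326 at day 10 (173 and 153), 329 at days 19 to 23 (172 and 157) and 354 in late cells (196 and 158). In the male line it called 353 (204 and 149), 274 (136 and 138), 279 (129 and 150) and 331 (159 and 172). Calls in the same direction in both lines, which share no libraries, numbered 219 at day 4, 187 at day 10, 204 at days 19 to 23 and 221 in late cells. Independent lists of those sizes would share 38.3 higher and 33.4 lower in late cells, where 106 and 115 were shared. Deviations of the same stage and experiment correlated between the lines at 0.130 to 0.554, which these independent values leave out. Opposite calls were made for miR-351-5p and miR-344f-3p at day 10 and for miR-503-5p and miR-344f-3p in late cells, named after their values were seen. Scaling to total counts moved the late share of higher calls from 55.4% to 65.7% (female) and from 48.0% to 68.9% (male), the share at days 19 to 23 from 52.3% to 68.6% and from 46.2% to 69.2%, and that at female day 4 from 62.6% to 48.1%. DESeq2's size factors (RLE) moved the male day 4 share from 57.8% to 46.1%. Leaving out 1 library changed several counts by more than 1.5 times. The female day 10 count was 215 without replicate 2 of day 10, and the male day 4 count 232 without replicate 2 of day 4. Male day 10 had 161 without replicate 3 of day 10 and 181 without day 0 replicate 2, male days 19 to 23 had 176 and 161 without replicates 2 and 3 of that stage, and late male cells 219 and 191 without replicates 2 and 3 of theirs.

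Next, the lines were compared at each stage. At day 0 the female line carried a large amount of a set of X-linked miRNAs known from testis, encoded between Fmr1 and Slitrk2 (chromosome X, 66776757 to 66839125 for those named), and the male line almost none. They took 7.54 ± 0.613% of all female counts and 0.0258 ± 0.0300% of male counts. The most abundant, miR-871-3p (66810428 to 66810504, intergenic), stood at 21687 ± 5383 CPM against 75.0 ± 85.7 in the male line (female over male log2 8.18 ± 1.24, adjusted p = 0.00055), followed by miR-465c-5p at 12627 ± 479 against 38.6 ± 45.0 and miR-470-5p at 11781 ± 1243 against 55.8 ± 68.3 CPM. All 29 measured members were higher in the female line at day 0 and at day 4, over all miRNAs and adjusted over the list alone. Their median log2 ratio was 8.33 at day 0 and 6.41 at day 4 with members under 3 counts in the male group set to that floor (fitted 8.36 and 6.45). By camera the adjusted p was 1.01e-61 at day 0, which held with an estimated correlation (adjusted p = 0.00868), and 4.84e-40 at day 4, which did not (adjusted p = 0.116 with an estimated correlation). The day 4 calls of single members depended on which libraries were kept, as given below for all miRNAs. Counts of the 3p arms of miR-465a, miR-465b and miR-465c, which are near-identical copies, stood close to 1 to 2 to 2 across the libraries. These are also their numbers of gene copies. Their single values are therefore uncertain, and these 3 of the 29 members cannot be read as separate measurements.

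The female cluster was lost during differentiation. Its share fell to 0.962 ± 0.669% at day 4, 0.0412 ± 0.0217% at day 10, 0.0119 ± 0.00994% at days 19 to 23 and 0.00214 ± 0.0000421% in late cells, where 373 counts were left in the group. At day 4 15 of 29 members were lower than at day 0 (23 adjusted over the list alone), and all 29 at each later stage. In late cells 9 members had 0 counts. Against the floor of 3 counts over the group, miR-471-5p was at least 2059.9-fold, miR-883b-3p at least 931-fold, miR-743b-5p at least 909.6-fold, miR-471-3p at least 909-fold and miR-883b-5p at least 692-fold lower than at day 0. Of the abundant members miR-871-5p went from 4715 ± 1129 to 0.482 ± 0.295 CPM (-13.26), miR-465b-5p from 5023 ± 362 to 0.561 ± 0.0202 (-13.10), miR-878-5p from 3892 ± 11.9 to 0.595 ± 0.190 (-12.63), and miR-743a-3p from 367.3 ± 239 CPM to 1 count. The median over the cluster with low members at the floor was a log2 level lower by 11.6 in late cells (camera adjusted p = 1.10e-23; adjusted p = 0.131 with an estimated correlation). In the male line, from far lower levels, 16 members were lower in late cells than at day 0 (17 adjusted over the list alone; adjusted p = 0.000293, and adjusted p = 0.678 with an estimated correlation), among them miR-470-5p (-6.63) and miR-871-3p (-5.57). The male day 0 level rested mainly on replicate 2, with 6348 counts of the cluster against 716 in replicate 3. Without male day 0 replicate 2 the late changes of miR-470-5p and miR-871-3p were -3.79 and -3.24, the median of the list was -2.24 (adjusted p = 0.0452), and its calls at male days 10 (0.192) and 19 to 23 (0.390) ended.

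X-linked miRNAs outside the testis cluster split into groups that differed in direction. The miR-322 cluster (53047997 to 53054349) was higher in female than in male cells at day 0. Here miR-351-5p stood at 3806 ± 574 against 404 ± 282 CPM (3.24 ± 0.49, adjusted p = 0.00055) and miR-322-5p at 992 ± 31.3 against 188 ± 62.7 CPM (2.40), while miR-450b-5p missed the threshold (1.60, adjusted p = 0.0549). Of 12 members 6 were called (10 adjusted over the list alone), with a median of 2.00 (camera adjusted p = 1.09e-08, and 0.0323 as adjusted p with an estimated correlation). From day 0 to day 4 9 of the 12 rose in the male line (median 1.99, adjusted p = 0.00244; adjusted p = 0.356 with an estimated correlation), and in late male cells 10, with miR-351-5p up by 2.91 and miR-322-5p by 2.55. The female medians were -0.26 at day 4 and 0.12 in late cells, without a call (adjusted p = 0.434 and 0.999). In the opposite direction, the miR-106a cluster (52741693 to 52742567), a paralogue of the miR-17-92 cluster, was lower in female cells at day 0. There miR-363-3p stood at 1009.7 ± 88.8 against 4146 ± 194 CPM (-2.04 ± 0.38, adjusted p = 0.00192), and miR-20b-5p, miR-18b-5p and miR-106a-5p differed by -2.04, -2.03 and -1.95. Of 8 members 6 were lower (8 adjusted over the list alone; median -1.87, adjusted p = 1.45e-07, and 0.11 as adjusted p with an estimated correlation). By day 4 all 8 rose in female cells (median 2.51; adjusted p = 0.000179, and 0.374 as adjusted p with an estimated correlation) and 4 in male cells (median 1.05, adjusted p = 0.113).

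Taken as 1 list, 91 X-linked miRNAs were higher in female cells at day 0, with 38 higher and 6 lower by edgeR (51 and 8 adjusted over the list alone). The median was 1.74 (camera adjusted p = 2.30e-28, and 0.00868 as adjusted p with an estimated correlation). At day 4 29 were higher, every one of them in the testis cluster, and the median was 0.48 (adjusted p = 0.000236; 0.607 as adjusted p with an estimated correlation). At day 10 it was 0.18 (adjusted p = 0.0257; 0.797 as adjusted p with an estimated correlation), which missed the threshold without a filter on low counts (0.112), without female day 10 replicate 2 (0.0995) and without male day 10 replicate 2 (0.136). Without female day 10 replicate 3 the median was -0.15. Between the 42 members outside the testis, miR-322 and miR-106a clusters the day 0 median was 1.07, with 32 above and 7 below 0, 3 at 0 for lack of counts in either line, and 3 called.

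**Figure D3:**
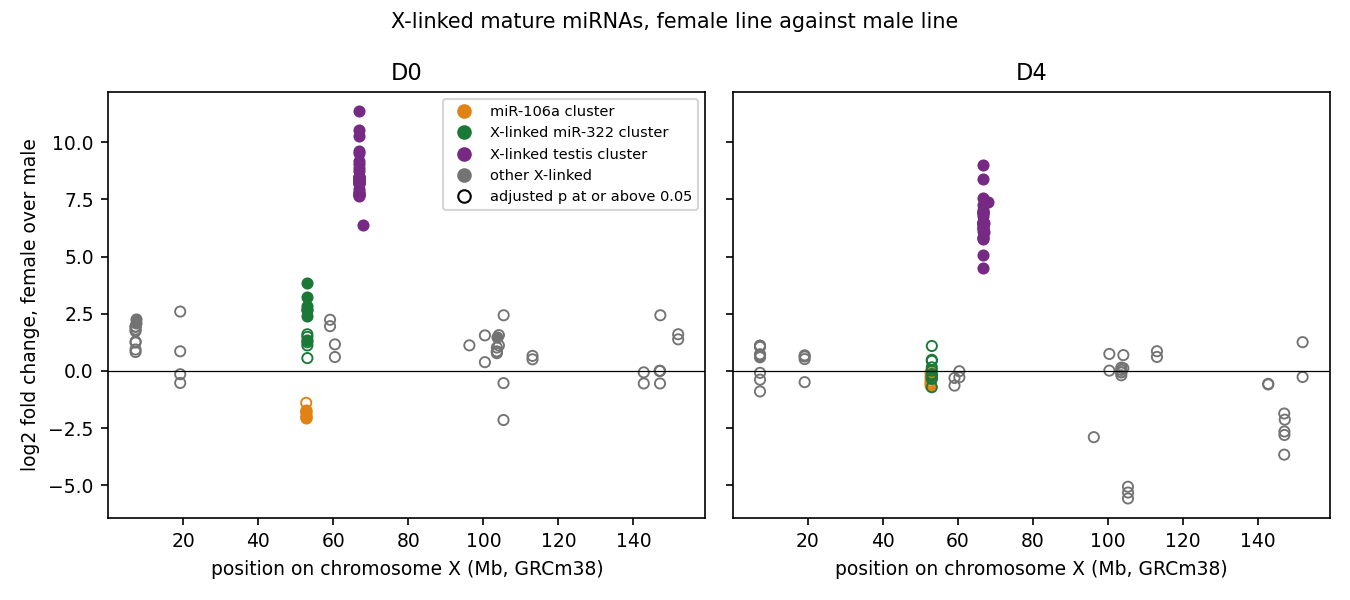
Female over male log2 ratio of 91 X-linked miRNAs against chromosome X position (Mb, GRCm38) at day 0 and day 4, coloured by cluster, with filled points for adjusted p below 0.05. At day 0 44 are called and at day 4 29, and the testis cluster stands highest at both days.

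By edgeR 71 miRNAs differed between the lines at day 0, 54 of them higher in female cells, and 41 at day 4, 38 of them higher. Outside the X-linked list 27 were called at day 0. Female cells had more let-7f-5p (1.56), let-7a-5p (1.45) and let-7b-5p (4.37) and less miR-141-3p (-2.52), miR-200c-3p (-1.32), miR-31-5p (-1.94) and miR-126-3p (-1.40). Of the 2 genes of let-7f-5p, 1 lies on the X chromosome, and reads of the copies cannot be told apart. Of the let-7 family 6 members were higher at day 0 (10 adjusted over the list alone; median 1.23, camera adjusted p = 3.49e-05, and 0.281 as adjusted p with an estimated correlation). Of the miR-200 family 2 were lower (median -1.32, adjusted p = 5.68e-05; 0.281 as adjusted p with an estimated correlation). Lower in female cells at day 4 were miR-670-3p (-2.72), miR-874-3p (-1.88) and the rare miR-653-3p, named after their values were seen. With the testis cluster taken out of the libraries, 35 miRNAs were called at day 0 (19 higher, 16 lower) and 0 at day 4, where 134 had an unadjusted p under 0.05. That setting was chosen after seeing the data. With a replicate block within stages, also chosen after seeing the data, the counts were 117 and 109, and DESeq2 called 78 at day 4. The day 4 count fell to 13 without female replicate 2, 18 without male replicate 2 and 0 without male replicate 3 of that day. With total-count scaling the share of higher calls at day 4 was 76.3% instead of 92.7%.

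From day 10 on edgeR called 0 miRNAs between the lines at each stage. In the later windows the sampling days differed between the lines. Female cells were taken at days 23 and 21 and male cells at days 21 and 19, replicates 2 and 3 in turn. Late female cells were of day 29 and late male cells of days 27 and 30. Line and day therefore cannot be separated in any comparison of the lines at days 19 to 23, nor fully in late cells. At an unadjusted p under 0.05 there were 97 at day 10, 60 at days 19 to 23 and 63 in late cells, and DESeq2 called 29, 2 and 4. At day 10 the block gave 17 calls within the whole series and 23 within stages, total-count scaling 9, no filter 10, the 10 CPM filter 3, and leaving out male day 10 replicate 2 gave 1. At days 19 to 23 the block within stages gave 2 and total-count scaling 1, and in late cells the block within stages gave 1. As lists, the Dlk1-Dio3 miRNAs were higher in female cells at each of these stages, with medians of 0.63, 0.65 and 0.81 (camera adjusted p = 1.05e-08, 6.42e-13 and 1.83e-23) against -0.04 at day 0. With an estimated correlation these were adjusted p = 0.523, 0.171 and 0.066, and the day 10 call ended without female day 10 replicate 2 (0.0995). The testis cluster had a median of 5.31 at day 10 (adjusted p = 9.26e-26; adjusted p = 0.408 with an estimated correlation), and 25 members passed adjusted over the list alone. At days 19 to 23 it took 0.0119 ± 0.00994% of female and 0.00212 ± 0.000658% of male counts (adjusted p = 1.59e-05; adjusted p = 0.706 with an estimated correlation), and in late cells 0.00214 ± 0.0000421% and 0.000838 ± 0.000463% without a call (adjusted p = 0.216). The miR-302 cluster was lower in female cells at day 10 (median -1.02, adjusted p = 2.90e-05; 0.66 as adjusted p with an estimated correlation).

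Averaged over the 5 stages, female cells had more of the testis cluster and of Dlk1-Dio3 and let-7 miRNAs. The highest ratios were those of miR-743a-3p, miR-743b-3p and miR-465a-5p, which had 3 counts or fewer in some groups, of miR-465c-5p (5.04), miR-470-5p (5.00 ± 0.59, adjusted p = 5.16e-05), miR-871-3p (4.77) and miR-741-3p (4.71), and of the 3p arms of miR-465a, miR-465b and miR-465c. Male cells had more miR-210-3p (-1.46 ± 0.31, adjusted p = 0.00781), which is induced by hypoxia, along with miR-210-5p (-1.30), miR-92b-3p (-0.99), miR-20b-5p (-0.92), miR-582-3p (-0.91), miR-101a-3p (-0.90 ± 0.14, adjusted p = 0.000738), miR-9-5p (-0.86), miR-106a-5p (-0.80), miR-31-5p (-0.73) and miR-301b-3p (-0.72). Of the lists, 41 Dlk1-Dio3 miRNAs were higher (59 adjusted over the list alone; median 0.51, camera adjusted p = 3.98e-11), 12 let-7 miRNAs were higher (14; 0.65, 0.000217) and 5 of the miR-106a cluster lower (6; -0.63, 1.62e-05). With an estimated correlation these had adjusted p = 0.285, 0.357 and 0.285. EdgeR called 150 miRNAs, 113 higher and 37 lower, of which 49 differed by more than 2-fold. The share of higher calls was 75.3%. With RLE 56 were higher and 56 lower, and with total-count scaling 49 and 54. With the testis cluster left out, a setting chosen after seeing the data, 89 were called (38 higher, 51 lower), and with the block within stages 229. Without single libraries the count lay between 71 and 121, and it was under 100 without 12 of the 20. These were the female libraries of day 0 replicate 2 (81), day 4 replicate 2 (97), day 10 replicate 3 (95), days 19 to 23 replicate 2 (79) and late replicates 2 (86) and 3 (71). The male ones were day 4 replicates 2 (94) and 3 (98), day 10 replicate 2 (96), days 19 to 23 replicates 2 (86) and 3 (88) and late replicate 3 (81). Single calls ended for miR-743a-3p without late female replicate 3 (adjusted p near 1) and miR-465a-5p without late female replicate 2 (0.0807). Without late male replicate 3 they ended for miR-210-5p (0.0509), miR-9-5p (0.0626), miR-31-5p (0.0523) and miR-301b-3p (0.0504), and for miR-9-5p also without female day 4 replicate 3 (0.0510).

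Whether the change over time differed between the lines was tested as an interaction. In late cells against day 0, female minus male, 3 X-linked miRNAs were called: miR-465b-5p (-7.69 ± 1.56, adjusted p = 0.0488), miR-351-5p (-3.54 ± 0.65, adjusted p = 0.0488) and miR-503-5p (-4.96, adjusted p = 0.0488). The last was below the abundance set for naming and was named after its value was seen. Of the 3, miR-465b-5p belongs to the testis cluster. In late male cells 10 of the 29 members of that cluster had 0 counts, which limits how far a male fall can be seen. From day 0 to late cells miR-351-5p went from 3806 ± 574 to 2457 ± 22.5 CPM in the female line, without passing the test, and rose from 404 ± 282 to 3032 ± 77.0 CPM in the male line. The count of 3 was 18 with the replicate block, 39 with the block within stages and with DESeq2, 9 with RLE, 13 with total-count scaling, 17 without a filter and 8 at 10 CPM or more. It was 0 without day 0 female replicate 2 or 3, late female replicate 2 or 3 or late male replicate 3, 1 without late male replicate 2, 5 without day 0 male replicate 3 and 12 without day 0 male replicate 2. All 3 missed the threshold without day 0 female replicate 2 (adjusted p = 0.0609) and late female replicate 2 (0.267). Without late male replicate 2 miR-465b-5p had 0.149 and the others 0.0655, and without late male replicate 3 these were 0.141 and 0.0982. Without replicate 3 of female day 0 miR-503-5p had 0.0921 and the others 0.0663, without late female replicate 3 these were 0.205 and 0.178, and without male day 0 replicate 3 miR-503-5p had 0.0957. A joint test over the 4 later stages called 0 miRNAs by edgeR (78 at an unadjusted p under 0.05), 47 by DESeq2, 12 with the replicate block, 10 with the block within stages and 3 without day 0 male replicate 2.

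A further difference between the lines concerned the rodent-specific cluster in an intron of Sfmbt2 on chromosome 2, whose many copies share reads. At male day 4 43 of 56 members fell (49 adjusted over the list alone), with a median of -2.14 (camera adjusted p = 6.07e-15; 0.356 as adjusted p with an estimated correlation). Summed over the tested members, the cluster went from 3331.5 ± 631 CPM at day 0 to 736 ± 198 at day 4 and 2322 ± 288 at day 10 in the male line. In the female line it stood at 3079 ± 488 and 2234 ± 464.8 CPM at days 0 and 4. Among male members miR-467a-5p (10 gene copies) went from 512 ± 170.1 to 113 ± 49.4 CPM (-2.18 ± 0.45, adjusted p = 0.00176), miR-669a-5p (12 copies) changed by -2.34, miR-467c-5p (10473931 to 10474027) by -1.92, and miR-466b-3p missed the threshold (-1.27 ± 0.51, adjusted p = 0.0544). In female cells 2 fell at day 4 (median -0.44, adjusted p = 0.0301; 0.681 as adjusted p with an estimated correlation), a call that ended with total-count scaling (0.0656), at 10 CPM or more (0.0723), without female day 4 replicate 2 (0.198) and without female day 0 replicate 3 (0.149). At day 4 the list was higher in female than in male cells (median 1.65, 4 called, 46 adjusted over the list alone; adjusted p = 2.70e-18, and 0.499 as adjusted p with an estimated correlation).

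MiRNAs of the Hox clusters, which mark position along the body axis, took a smaller mean share of counts than at day 0 in every later group except late male cells. At day 10 6 of 10 were lower than at day 0 in the male line (8 adjusted over the list alone; median -4.60, camera adjusted p = 0.0052, and 0.617 as adjusted p with an estimated correlation). In the late male libraries miR-10b-5p (in introns of Hoxd3 and Hoxd4) stood at 453 CPM in replicate 2 and 12948 CPM in replicate 3, miR-10a-5p at 46.6 and 2614, miR-196a-5p at 9.02 and 278 and miR-615-3p at 6.44 and 88.4 CPM. In late cells the list was lower in the female line (median -4.02, 0 called, 7 adjusted over the list alone; adjusted p = 4.48e-10, and 0.177 as adjusted p with an estimated correlation). Without late male replicate 3 that median was -0.07 (adjusted p = 0.120). The late male rise of miR-10a-5p (5.14 ± 1.45, adjusted p = 0.0121) and its rise since day 10 rest on the same group.

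Markers of other cell types were measured in the same way. Among the mesenchymal and fibroblast miRNAs miR-21a-5p (an exon of Vmp1) rose from 2429 ± 229 to 13844 ± 679 CPM in female (2.51) and from 2526 ± 40.8 to 7984 ± 519 CPM in male cells (1.66) and miR-199a-3p rose in female cells (3.99), while miR-143-3p fell there (-1.92). The list was not called (smallest camera adjusted p over all contrasts 0.131), and its share went from 0.748 ± 0.278% to 1.89 ± 0.289% and from 0.659 ± 0.180% to 1.42 ± 0.283% in late cells. Of the endoderm list, apart from miR-375-3p, miR-192-5p and miR-194-5p fell in late cells (female -1.52 and -1.71, male -2.45 and -2.26). In late female cells the list's median (-0.05) and mean (2.10) differed in sign, and it was never called (smallest adjusted p 0.102). Of the muscle list miR-208b-3p and miR-133a-3p rose (2.73 and 2.32 female, 4.16 and 3.68 male) against the fall of miR-499-5p, and the list was lower in female than male cells at days 19 to 23 (median -0.99, adjusted p = 0.00157; 0.0855 as adjusted p with an estimated correlation). Of the blood and endothelial markers miR-142-5p fell (-4.95 and -4.11), and 5 of 13 were lower in late male cells (adjusted p = 0.0383; 0.454 as adjusted p with an estimated correlation). That call ended at 10 CPM or more (0.207), without male day 0 replicate 2 (0.187) and without late male replicate 3 (0.0625).

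Of the remaining lists, the neural miRNAs were slightly lower in female cells averaged over stages (median -0.21, adjusted p = 0.0302; 0.285 as adjusted p with an estimated correlation) and at day 4 (median -0.67, adjusted p = 0.00201; 0.135). The averaged call ended at 10 CPM or more (0.266), without female day 4 replicate 2 (0.0618), days 19 to 23 replicate 2 (0.0560), day 0 replicate 3 (0.0562) and day 10 replicate 3 (0.0531). The miR-17-92 and miR-106b-25 miRNAs, a list that also holds arms with X-linked copies, were lower in female cells at day 0 (median -0.52, adjusted p = 0.0024; 0.54 as adjusted p with an estimated correlation), a call lost without male day 0 replicate 2 (0.146), with miR-93-5p (an exon of Mcm7) at -1.28. Neither the miR-183 cluster (smallest adjusted p 0.314) nor the miR-29 family (0.194) was called in any contrast. Entries reported to be fragments of ribosomal or transfer RNA, a sign of RNA quality, were not called as a list (0.249). Their share was 0.212 ± 0.0179% at day 0 and 1.12 ± 0.813% in late cells of the female line, and 0.205 ± 0.192% and 0.689 ± 0.300% in the male line, and miR-5115 rose in late female cells (3.30 ± 0.95, adjusted p = 0.0111). The late groups, in which miR-375-3p and miR-99b-5p had risen, also had the highest mean shares of such fragments in both lines. At days 19 to 23 the fragments took 0.378 ± 0.0246% of female and 0.329 ± 0.00232% of male counts. The miR-99/100 and miR-125 list then took 4.15 ± 1.63% and 3.73 ± 0.407%, and in late cells 3.34 ± 0.434% and 4.06 ± 0.884%.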

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

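The tests of explanations in this part, with their bounds, and the day 4 interaction were chosen after seeing the results; other bounds were considered, and where they matter this is said. Results stand here because the change over time differed between the lines by a test of that difference, or because counts were seen in miRNAs that only the female table holds.

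In late cells against day 0 the female change was below the male change for miR-465b-5p (-7.69), miR-503-5p (-4.96) and miR-351-5p (-3.54), each at an edgeR adjusted p of 0.0488. As lists by camera, the median difference was -7.20 for the testis cluster (adjusted p = 1.48e-19), -1.80 for the miR-322 cluster (1.54e-11), -1.73 for all X-linked miRNAs (2.64e-18), -5.51 for the Hox miRNAs (7.06e-06) and -0.61 for let-7 (0.0197). It was 1.56 for the miR-106a cluster (0.00013), 1.92 for the miR-200 family (2.58e-06) and 0.84 for Dlk1-Dio3 (1.10e-07). With an estimated correlation only the X-linked and miR-322 lists kept an adjusted p under 0.05 (0.0253 each). For the testis cluster the male fall was limited by depth. In late male cells 10 of its 29 members had 0 counts and 7 had 1 to 3. With low members at the floor, the median log2 level was lower by 5.16 in late male cells (22 members above the floor). In late female cells it was lower by 11.6. The day 0 gap between the lines was 8.33, so the difference in change cannot be told apart from that starting gap. The Hox difference was -1.18 without late male replicate 3 (adjusted p = 0.113). That of let-7 missed the threshold without late female replicate 2 (0.104), female day 0 replicate 3 (0.0977), male day 0 replicate 3 (0.110) and late male replicate 3 (0.5001).

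At day 4 edgeR called 0 miRNAs for this difference (118 at an unadjusted p under 0.05; 3 without male day 0 replicate 3), and DESeq2 was not run on it. The lists had medians of 1.52 (miR-302 cluster, camera adjusted p = 0.00443), 1.44 (miR-106a cluster, 0.000329), -0.16 (let-7, 0.0337), 1.49 (miR-200 family, 0.00205), 0.64 (Dlk1-Dio3, 0.000123), 1.60 (Sfmbt2 cluster, 1.16e-18), -1.55 (X-linked, 6.54e-12), -1.93 (miR-322 cluster, 7.05e-12) and -1.89 (testis cluster, 6.47e-08). With an estimated correlation only the miR-322 cluster stayed under 0.05 (0.0340).

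Of the miRNAs that only the female table holds, 8 had counts above what 0 allows, over 10 libraries: miR-742-5p 339, miR-201-5p 271, miR-742-3p 102, miR-880-5p 21, miR-547-5p 17, miR-133b-5p 11, miR-201-3p 10 and miR-675-5p 4. For miR-742-5p 85 and 210 of them were in the day 0 libraries, and for miR-201-5p 57 and 164. The 3p arms of miR-880 and miR-547 are in the testis cluster list, so their 5p arms are further members of it that were not compared between the lines.

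The male line held few reads of the testis cluster, most of them in day 0 replicate 2. A carry-over of the same share into every male library of experiment 2 was excluded, as the cluster's share at day 0 was 49.0 times that at day 10. That ratio does not cover carry-over in proportion to the female sample of the same day. At days 0, 4 and 10 the male share was 0.661%, 1.43% and 1.70% of the matched female share in replicate 2. In replicate 3 it was 0.0575%, 1.22% and 5.21%. A mixture of finished female libraries of days 0 to 10 could explain the male day 4 reads, since the best mixture left a chi-square per degree of freedom of 2.14 (1.06 in replicate 3). It fitted day 0 poorly, at 10.7 (4.45 in replicate 3). A bound of 5 instead of 3 would leave replicate 3 undecided, and a bound of 2 would also exclude day 4 of replicate 2. These chi-square values allow for counting error only. Expression in the male cells and female RNA or cells present before library preparation both remain open.

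X-linked miRNAs outside the testis cluster were higher in female cells at day 0 (median 1.11) and near the male level at day 4 (-0.17), which would be consistent with a second active X chromosome that is silenced on differentiation. Loss of a second X predicts a female fall by day 4 only where differentiation itself leaves the level unchanged. The miR-322 cluster rose in male cells (1.99; female -0.26), so this condition was not met and the test cannot decide. For the other X-linked miRNAs the female median was -0.0224 with an SD of 2.61 across miRNAs. That SD is the spread of different miRNAs, not the error of their median, so a bound set against it cannot decide. The miR-106a cluster was lower in female cells (-1.87), against a uniform dosage effect.

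The Sfmbt2 cluster was lower at male day 4. The median stayed at -1.98 or below without any 1 library, was -2.08 with total-count scaling, and the summed CPM changed by -2.18, so neither 1 library, scaling nor the sharing of reads among copies accounts for it. The design gives both day and line as a biological reading, and a state that male cells pass through at day 4 may be 1 such reading, which these tests (-2.18) leave open.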

How the results depend on the processing

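Tests under a block within stages and without the testis cluster were chosen after seeing the results. Of the counts, 109 stayed within 1.5 times under other settings and 35 did not, and 101 and 35 when 1 library was left out. All 580 values of named miRNAs kept direction and side of the threshold under other settings. For lists direction means that of the camera test, not the sign of the median: 608 values stayed and 30 were weaker. Without 1 library 638 named values stayed and 26 were weaker, and 566 list values stayed, 65 were weaker and 1 reversed: the miR-290 cluster, female against male at days 19 to 23, had a median of 0.0683 without PGK_D19to23 replicate 2 (camera adjusted p = 0.614), the highest of a range from -0.774 without PGK_D19to23 replicate 3. The cause was not tested.

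RLE scaling gave 9 calls in the late interaction (3 in the main analysis). Total-count scaling gave 13 there, 9 between lines at day 10 and 1 at days 19 to 23 (0 and 0). Without a filter there were 17 in the late interaction, 10 between lines at day 10, and 15 each in female and male late against day 10 cells (4 and 6). At 10 CPM or more there were 8 and 3 in the late interaction and between lines at day 10, with fewer miRNAs tested. DESeq2 gave 39 in the late interaction, 47 in the joint test (0), 78 (41), 29, 2 and 4 between lines at days 4, 10, 19 to 23 and late, and 33 and 28 for late against day 10. Each line alone gave 19 and 3 there, from fewer libraries. Without the testis cluster 89 (150) were called averaged over stages, 35 (71) at day 0 and 0 (41) at day 4. The 29 members taken out account for only part of this, and the cause of the rest was not tested.

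With the replicate block, whose numbers pair samples by experiment, edgeR called 18 in the late interaction, 12 in the joint test, 17 between lines at day 10 and 28 in late against day 10 female cells. The list calls for miR-34 in late female cells (adjusted p = 0.0582) and miR-200 at male days 19 to 23 (0.05375) ended. The block within stages gave 229 averaged over stages, 117, 109, 23, 2 and 1 between lines from day 0 to late, 39 in the late interaction and 10 in the joint test, and ended miR-106a between lines in late cells (0.0523). The blocks ended no other main call of a list or named miRNA, and single gains were not listed.

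Leaving out 1 library, female calls against day 0 ranged from 220 to 272 (318 in the main analysis) at day 4, 215 to 295 (326) at day 10, 238 to 299 (329) at days 19 to 23 and 240 to 311 (354) late. Male calls ranged from 232 to 290 (353), 161 to 207 (274), 161 to 243 (279) and 191 to 263 (331). Late against day 10 had 3 to 6 (female) and 2 to 20 (male). Between lines there were 53 to 84 at day 0, 0 to 30 at day 4, 0 to 1 at day 10, 0 to 0 later, and 71 to 121 averaged. The late interaction had 0 to 12 and the joint test 0 to 3. Shared late calls ranged from 155 to 203 (221) and list calls from 113 to 127 (118).

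Total-count scaling shifted the median of all miRNAs to 0.71 and 0.68 in male late and days 19 to 23 cells against day 0, 0.42 and 0.58 in female ones, 0.29 and 0.20 at female and male day 10 and -0.20 at female day 4. It turned the medians of the X-linked list at female days 19 to 23 (-0.46 to 0.07) and of miR-200 at male days 19 to 23 (-0.43 to 0.25). Depth limits the testis cluster in late cells, with 373 counts left in the female and 159 in the male group. Without PGK_D10 replicate 3 the median of the X-linked list between lines at day 10 turned (0.18 to -0.15), and without E14_D27to30 replicate 2 that of miR-302 between lines in late cells (-0.36 to 0.14).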

Other observations

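The tests in this part were chosen after seeing the results. Some further single miRNAs, named after their values were seen, differed between the lines. Averaged over stages, miR-335-3p and miR-335-5p were higher in female cells (1.91 and 1.38) and miR-483-5p lower (-2.57). At day 0 miR-344d-3p (3.95), miR-142-3p (2.31) and let-7c-5p (2.98) were higher in female cells, and miR-149-5p (-1.82) and miR-126-5p (-1.50) lower. At day 4 miR-215-5p was higher (2.04).

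Other splits of the 20 libraries into 10 and 10 within stages were tried with the averaged contrast in edgeR. The real split by line called 150 miRNAs, and 1 of 100 splits, the real one, called as many. The highest other split called 67, or 32 among the 19, the real one included, that part as many pairs of libraries of the same stage and experiment. For the joint interaction the real count was 0, so 100 of 100 splits called as many, which was fixed in advance and decides nothing. The highest other called 55, also among the 19 that part as many pairs. Splits that swap the lines between stages turn a line difference into an interaction, so 55 is not a value without effects. Split by experiment, the counts were 18 and 0.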
